A study of Mus musculus with 6 samples.

How the data were processed

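Messenger RNA abundance was measured by RNA sequencing in 3 murine pancreatic ductal adenocarcinoma cell lines named 2838c3, 6419c5 and 6499c4. Per the labels' protocols, each line received the solvent DMSO (vehicle) or 250 nM G-1, an agonist of the G protein-coupled oestrogen receptor GPER, for 16 hours. Total RNA was purified on columns and made into libraries with an NEBNext Ultra kit, and the labels do not say how ribosomal RNA was removed. There was 1 library per line and treatment, 6 in all, and each library was used.

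The deposited values are FPKM (fragments or reads per kilobase of gene length, scaled to the size of each library), 1 table of 24421 gene symbols by 6 libraries. The unit comes from the name the authors gave the table and was checked on the values. STAR and DESeq2 are named in the submitters' processing notes, with no role stated for either. The genome build, the annotation, the strandedness and the rule for counting reads are not given in the sources used here. Within a gene and a library the deposited FPKM values move in equal steps, so whole reads could be recovered. For all 15712 genes above 0 in any library, the 6 values were whole multiples of a step within 0.01 reads. Median-of-ratios size factors computed from these reads had the ratios of the scale behind the FPKM values to within 3.3e-11, while ratios of read totals deviated by up to 10.2%. The library scale in the FPKM was therefore proportional to size factors, not to read totals. In simulated reads, 97.69% of 15167 genes were recovered exactly, and 98.27% of those with at least 60 reads. A gene whose reads share a common divisor can be recovered too low by that factor. 27 gene names had been turned into dates by a spreadsheet and 2 names were duplicated. None of 10 housekeeping genes was at 0 in any library.

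Reads in genes numbered 8890821 (vehicle) and 8645057 (G-1) in 2838c3, 7213624 and 5455990 in 6419c5, and 8567641 and 7484596 in 6499c4. A count of 0 allows up to 3 reads, which is 0.337 to 0.55 RPM over the 6 libraries. Read ratios of G-1 to vehicle used the recovered reads and the authors' scale, with exact 95% intervals from the binomial distribution. Floors and intervals cover counting error only.

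Values were analysed as log2(FPKM + 1) for the 10748 genes with a mean of at least 1 FPKM. G-1 was compared with vehicle in limma 3.58.1 (R 4.3.3) with cell line as block and a moderated variance that follows the mean level (2 residual and 5.35 prior degrees of freedom). The lines pair the libraries by design, and as a check the correlations between both libraries of a line, after centring each gene within its treatment group, were 0.906, 0.871 and 0.882 for 2838c3, 6419c5 and 6499c4. Lines were compared in pairs with treatment as covariate, from 2 libraries per line. Adjusted p-values follow Benjamini and Hochberg, with a threshold of 0.05. All limma and list tests were two-sided. Receptor genes were also tested one by one with an exact two-sided sign-flip permutation test over the 3 lines, whose smallest possible p is 0.25. Agreement between lines was measured across genes, which are not independent replicates, with Pearson's r and Spearman's rho.

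Before the data were examined, 33 gene lists were fixed, together with the comparisons, the tests, the alternatives not marked below as added and the rule for naming genes. The lists with at least 5 members at or above the level filter, 25 of them, were tested with camera (inter-gene correlation 0.01), and again with an estimated correlation and with fry. They cover aryl hydrocarbon receptor targets, cholesterol synthesis, cAMP/CREB-responsive genes, YAP/TEAD targets, lysosome genes, DNA replication, mitosis, MYC targets, p53 targets, the integrated stress response, endoplasmic reticulum chaperones, interferon-stimulated genes, MHC class I presentation, checkpoint ligands, cytokines and NF-kB, hypoxia and glycolysis, epithelial, mesenchymal, classical and basal-like tumour genes, tubulins, NRF2 targets, oxidative phosphorylation, ribosomal proteins and oestrogen receptor alpha response. The others are genes of the mitochondrial genome, replication-dependent histones and markers of 6 other cell types. Genes always named were Gper1, Esr1, Esr2, Cd274 and Myc. The rule then took up to 12 genes per direction for G-1, first those past the threshold with the same sign in all 3 lines, then others with the same sign ranked by their smallest difference over the lines. It took up to 6 genes per direction for each line, ranked by the smaller of the differences from both other lines, and up to 4 members per list with the largest mean difference, first those with the same sign in all lines. Genes without a name other than a clone or model number were passed over. Any gene named outside the rule is said to have been chosen after its values were seen. Several genes that the rule took are not reported here, and they stayed in every fit and list.

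The fit for G-1 was tested on simulated data with 200 changed genes. At a dispersion of 0.005 (10752 genes run), 90 of 99 genes changed by 1 on the log2 scale and 94 of 98 changed by 2 were recovered, with 8 false calls. At a dispersion of 0.02 (10743 genes run), 84 of 98 and 96 of 98 were recovered, with 15 false calls. Each changed gene was given a set change, so these shares do not cover genes whose response differs between lines. The adjustment is also easier to pass with 200 changed genes than in the real data, where 3 genes were called. The shares are therefore not the chance of finding such a change in the real data.

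Alternatives were pseudocounts of 0.1 and 0.01, no level filter and a filter at a mean of 5 FPKM, median-of-ratios and quantile scaling, moderation without the trend and with robust weights, no block, and leaving out each line or library. Added after the data were seen were limma-voom on the recovered reads (11223 genes with at least 60 reads), a loess correction (span 0.5) of each library for GC content and gene length, both together, and a fit without small RNA genes. GC content and loci came from GENCODE vM21 (GRCm38), and GC was known for 96.5% of the genes tested. Recovery and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The labels give no batch or date, so none could be tested.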

Results

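The data are 6 libraries from 3 murine pancreatic ductal adenocarcinoma lines, each with 1 vehicle and 1 G-1 library (250 nM, 16 hours), so that a group holds 3 libraries. Reads in genes ranged from 5455990 (6419c5, G-1) to 8890821 (2838c3, vehicle), and 13071 to 13627 genes were above 0 in a library. The 10 most abundant genes took 4.18 to 4.65% of the reads. The series asks how an agonist of the G protein-coupled oestrogen receptor GPER changes gene expression in these tumour cells. Between libraries of the same line, the median gene varied 1.98 to 4.82 times as much as counting noise alone would give, and between libraries of different lines with the same treatment 18.2 to 33.3 times. No treatment was repeated within a line, so the limma p-values of the FPKM test rest on the spread between the 3 lines, moderated by variances pooled over genes. Those of limma-voom lean far more on the pooled variances. Camera sets the genes of a list against the other genes, so its p-values do not measure the spread between lines alone. A difference between lines in their response could not be tested.

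Reads from the gene of the receptor that G-1 targets were not detectable at this depth. Gper1 had 0 reads in each of the 6 libraries, which allows up to 3 reads per library. In the GRCm38 annotation Gper1 lies on chromosome 5 from 139423151 to 139427800, on the plus strand inside an intron of a gene on the minus strand that had 223 to 283 reads per library, and no exon of that gene overlaps it. Whether the reads were counted by strand is not given in the sources used here. Esr1, the gene of oestrogen receptor alpha, had 6 and 5 reads (vehicle, G-1) in 2838c3, 27 and 24 in 6419c5, and 26 and 15 in 6499c4. Esr2, the gene of oestrogen receptor beta, had 1 read in all, in the vehicle library of 6499c4. The exact two-sided sign-flip test over the 3 lines gave p = 0.75 for Esr1, and 0.25 is the smallest these lines can give. For Gper1 and Esr2 the p of that test could only be 1, for lack of reads, and says nothing about a change. Cd274, which encodes the checkpoint ligand PD-L1, had 36 and 17, 78 and 57, and 33 and 40 reads in the same order of lines, a mean log2 difference of -0.09 (SE 0.18, n = 3 lines, adjusted p = 0.888). That difference was 0.10 without 2838c3. The oncogene Myc had 1478 to 2782 reads per library and a mean log2 difference of -0.01 (SE 0.06, adjusted p = 0.974), which was 0.02 without 2838c3.

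G-1 raised Cyp1b1, a cytochrome P450 gene induced through the aryl hydrocarbon receptor, in each of the 3 lines. Its level went from 1.71 to 8.11 FPKM in 2838c3, from 46.1 to 121 in 6419c5 and from 8.88 to 24.0 in 6499c4, with read ratios of 4.75 (95% interval 3.69 to 6.17), 2.62 (2.47 to 2.78) and 2.70 (2.41 to 3.04). The mean log2 difference was 1.49 (SE 0.10, n = 3 lines, adjusted p = 0.00656). Other targets of the same receptor were higher under G-1 in every line but did not pass over all genes. Cyp1a1, its classical target, went from 27 to 193 reads in 2838c3 (ratio 7.17, interval 4.78 to 11.2), from 0 to 115 in 6419c5 (at least 40.3-fold higher, the lower limit of the exact interval) and from 1 to 20 in 6499c4 (ratio 22.8, interval 3.65 to 947). Its adjusted p was 0.219 in the test on FPKM. Tiparp, which encodes an ADP-ribosyltransferase that restrains the receptor, had read ratios of 2.04, 2.42 and 1.71 (mean log2 difference 0.97, SE 0.10, adjusted p = 0.0627). Ahrr, the receptor's repressor, had ratios of 2.42, 2.14 and 3.31 (adjusted p = 0.349), and Aldh3a1 had 1.09, 1.16 and 1.06. In GRCm38, Cyp1b1 lies on chromosome 17 (79701537 to 79715061), Cyp1a1 on chromosome 9 (57687928 to 57703824) and Tiparp on chromosome 3 (65528410 to 65555518).

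**Figure D1:**
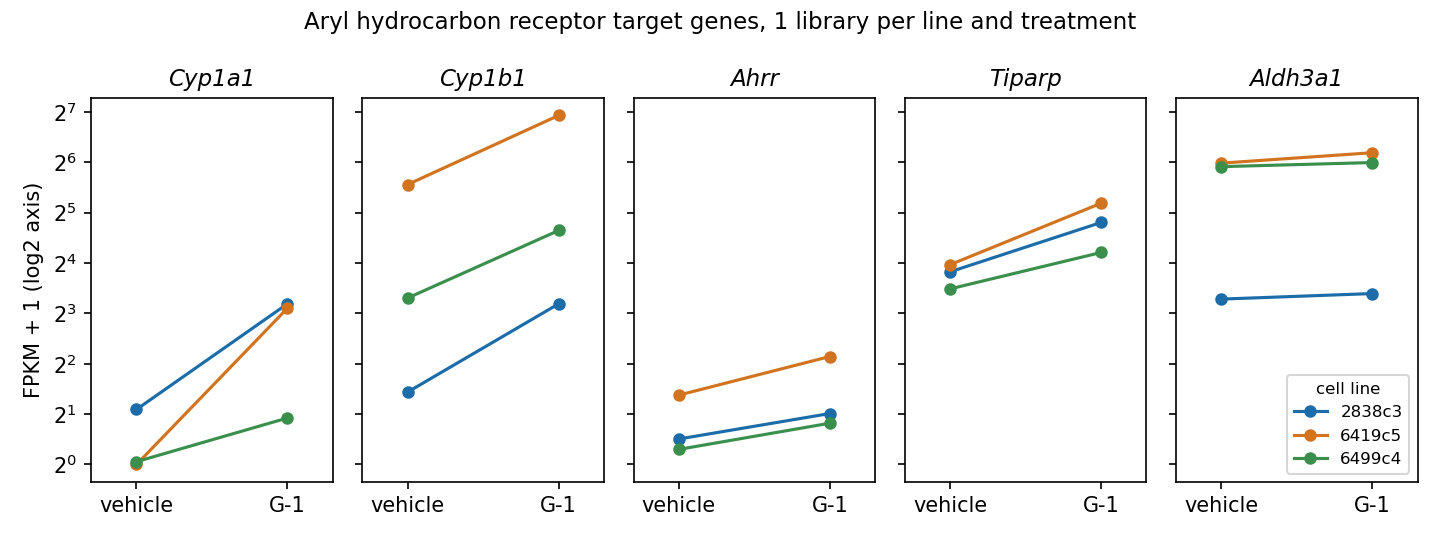
FPKM + 1 (log2 axis) of 5 aryl hydrocarbon receptor targets in the vehicle and G-1 library of each of the 3 lines, with a line joining both libraries of a cell line. Cyp1b1 goes from 1.71 to 8.11 FPKM in 2838c3 and from 46.1 to 121 in 6419c5, while Aldh3a1 differs by ratios of 1.06 to 1.16.

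The list of aryl hydrocarbon receptor targets had 5 members at or above the level filter, and each was higher in all 3 lines, where chance gives 1 gene in 8. Its median log2 difference was 0.97, and camera gave an adjusted p of 1.33e-08. With an estimated correlation the list had an adjusted p of 0.518, and with fry 0.113. One member passed over all genes and 4 (Cyp1a1, Cyp1b1, Ahrr and Tiparp) when adjusted over the list alone. The list kept its camera call when any 1 line was left out. The estimated correlation rests on 2 residual degrees of freedom, and with it 0 lists passed in any comparison. Even YAP/TEAD genes between 6499c4 and 6419c5, with 13 of 14 members past the threshold, had an adjusted p of 0.409 there. Values from that setting, here and for the lists below, therefore cannot show that a call is undone.

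Beyond Cyp1b1, the test over 10748 genes called a pair of small nucleolar RNA genes. Each lies inside a longer gene and overlaps an annotated exon of it, and how reads in such overlaps were assigned is not given in the sources used here. Snord12, inside Zfas1 on chromosome 2, fell by 0.90 on the log2 scale (SE 0.06, adjusted p = 0.00656), with 40 and 20, 24 and 10, and 32 and 15 reads. Snora81, inside Eif4a2 on chromosome 16, fell by 1.57 (SE 0.14, adjusted p = 0.0267), from 12, 11 and 8 reads to 3, 3 and 1. In all, 3 genes passed and 1081 had an unadjusted p under 0.05. Without the line block 0 genes passed in limma and 25 had an unadjusted p under 0.05. Limma-voom on the recovered reads, added after the data were seen, called 181 genes (123 higher, 58 lower), of which 163 had the same sign in all lines, 0 were small RNA genes and Cyp1b1 was the only one of the 3. There the adjusted p was 1.36e-15 for Cyp1b1, 7.81e-08 for Tiparp, 9.99e-06 for Cyp1a1, 0.0127 for Ahrr and 0.204 for Snord12, and Snora81 was under the read minimum. Corrected for GC content and gene length as well, the voom fit called 30 genes, 28 of them among the 181, and these 4 receptor targets stayed below 0.05 (5.69e-07, 7.51e-05, 0.0101 and 0.0484). Without 2838c3, 6419c5 or 6499c4 the voom fit called 131, 96 and 56 genes, of which 91, 78 and 45 were among the 181. A voom p as small as that of Cyp1b1, with 2 residual degrees of freedom, rests almost wholly on variances pooled over genes. Voom p-values thus reflect the spread between the 3 lines only weakly. Acta2 and Sox17 passed there without the same sign in all lines, and Sox17 had 0 reads in 2838c3. The call of Cyp1b1 held in 10 of 16 settings and ended with pseudocounts of 0.1 (adjusted p = 0.0772) and 0.01 (0.138), without the level filter (0.331) and without the variance trend (0.158). In the FPKM test it also ended without 6419c5 (adjusted p = 0.274), as did those of Snord12 (0.212) and Snora81 (0.26), and that of Snora81 also ended without 2838c3 (0.0945). Over all alternatives Snord12 was called in 9 of 15 and Snora81 in 4 of 12. These counts and that of Cyp1b1 include median-of-ratios scaling, which nearly repeats the scale of the FPKM values and could hardly change a call. After the GC and length correction in the FPKM test Snora81 had an adjusted p of 0.0692, with a log2 difference of -1.69. Cyp1a1 (0.0171) and Tiparp (0.0174) passed without 6499c4, and Tiparp also with the filter of 5 FPKM (0.0259), with robust moderation (0.0167) and without small RNA genes (0.0282).

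Genes with the same sign in all 3 lines that did not pass filled the rest of the rule, 11 higher (Cyp1a1 and Tiparp among them) and 10 lower. Among the higher ones were Neurl3, a ubiquitin ligase gene (log2 difference 0.66, SE 0.07, adjusted p = 0.0631), Bola1 (0.69, SE 0.08, adjusted p = 0.0845), the linker histone gene Hist1h1c (0.62, SE 0.08, adjusted p = 0.107) and the stress-induced cytokine gene Gdf15 (0.87, SE 0.14, adjusted p = 0.216). AW112010 (0.77) and Ppp1r35 (0.86) were also higher, and Rpph1 (1.66), Snord68 (1.89) and AF357399 (0.87) rest on few reads. Among the lower ones were Sprr1a, a cornified envelope gene (-0.51, SE 0.07, adjusted p = 0.175), Csf1, which encodes a macrophage growth factor (-0.42, SE 0.08, adjusted p = 0.287), the collagenase gene Mmp13 (-0.39, SE 0.08, adjusted p = 0.288), Layn (-0.74), Masp1 (-0.47), Sec16b (-0.47) and Pak6 (-0.42). The small RNA genes Mir682 (-1.32), Snord47 (-1.02) and Snora74a (-1.04) complete the set, with adjusted p from 0.271 to 0.349. Neurl3, Bola1, Hist1h1c, Gdf15, Ppp1r35, Sprr1a, Csf1 and Mmp13 were among the 181 genes called by voom. With the GC and length correction in voom Neurl3 (adjusted p = 0.00164), Sprr1a (0.0104) and Csf1 (0.0484) stayed below 0.05, and Bola1 (0.204), Hist1h1c (0.182), Gdf15 (0.211), Ppp1r35 (0.17) and Mmp13 (0.0579) did not. In the order given, the log2 differences of the genes that did not were 0.53, 0.53, 0.79, 0.87 and -0.41 in voom with the correction. Without it they were 0.71, 0.64, 0.98, 1.11 and -0.42.

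Genes of cholesterol synthesis and uptake were higher under G-1 as a list. The median log2 difference was 0.18 over 20 genes, 12 were higher in all 3 lines (1 gene in 8 by chance) and none was lower in all 3. Camera gave an adjusted p of 2.11e-08, against adjusted p = 0.518 with an estimated correlation and 0.185 with fry, where the list did not pass. None passed over all genes and 7 passed when adjusted over the list alone, among them Hmgcs1 (0.23, SE 0.07), Fdft1 (0.26, SE 0.08) and Mvd (0.24, SE 0.08). Mvk was at 0.24 (SE 0.10) and did not pass. After correction for GC content and length the list median was 0.16 (camera adjusted p = 2.39e-10).

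The list of cAMP/CREB-responsive and immediate early genes was also higher, with a median of 0.13 over 16 genes and 6 higher in all lines (camera adjusted p = 2.43e-04, adjusted p = 0.518 with an estimated correlation). With fry its adjusted p was 0.281. The median was 0.06 without 6499c4, 0.19 without 6419c5 and 0.25 with a filter of 5 FPKM. When adjusted over the list alone 5 passed, and none over all genes: Junb (0.45, SE 0.10) and Atf3 (0.26, SE 0.08), which encode AP-1 and ATF family factors, Areg (0.36, SE 0.09), an epidermal growth factor receptor ligand, Klf4 (0.34, SE 0.06) and Ier2 (0.25, SE 0.07). Targets of YAP/TEAD and matricellular genes were lower, with a median of -0.10 over 14 genes and 7 lower in all lines (camera adjusted p = 2.03e-04, adjusted p = 0.518 with an estimated correlation). With fry the adjusted p of this list was 0.147. Thbs1 (-0.33, SE 0.06), Ankrd1 (-0.30, SE 0.07), Ctgf (-0.29, SE 0.08) and Amotl1 (-0.28, SE 0.09) were the 4 that passed when adjusted over the list alone, and none passed over all genes. Without the line block camera gave an adjusted p of 0.227 for the YAP/TEAD list, and 4 of the 11 lists called with the block passed, those of aryl hydrocarbon receptor, cholesterol, cAMP/CREB and lysosome genes. Both lists, like that of cholesterol synthesis, kept their camera calls when any 1 line was left out.

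**Figure D2:**
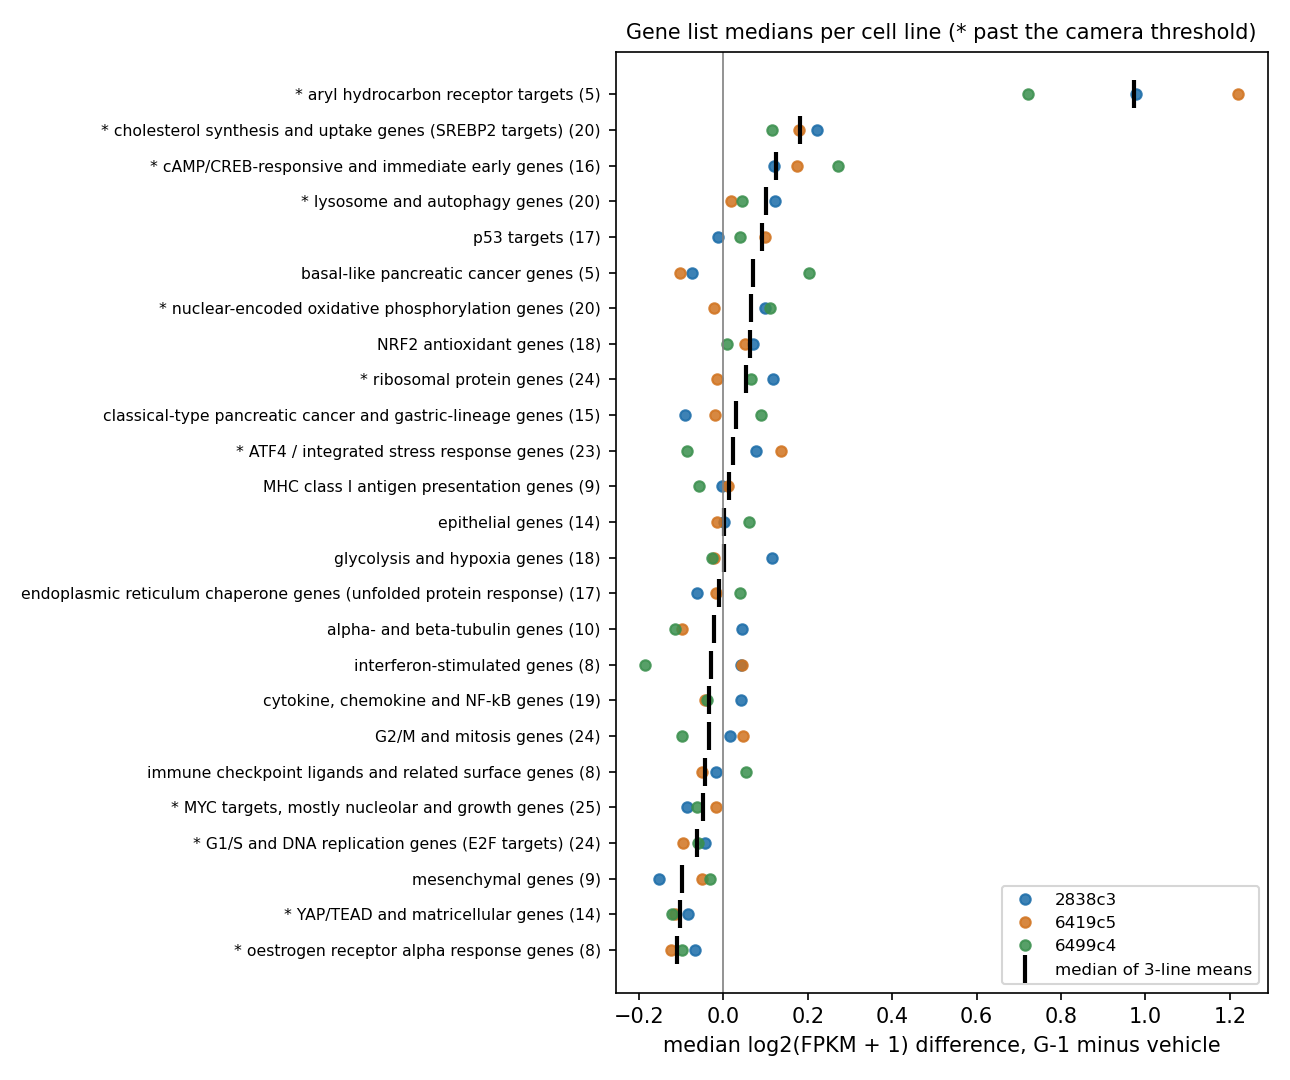
Median log2 difference (G-1 minus vehicle) of the members of each of the 25 tested gene lists in each of the 3 lines, with a black bar for the median over the 3-line means, the number of members in brackets and an asterisk where camera passed. Aryl hydrocarbon receptor targets lie at 0.98, 1.22 and 0.72 in 2838c3, 6419c5 and 6499c4, and cholesterol genes at 0.22, 0.18 and 0.12.

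Another 7 lists passed with camera by small medians, each with an adjusted p between 0.518 and 0.912 with an estimated correlation. Lysosome and autophagy genes were higher (median 0.10 over 20 genes, camera adjusted p = 0.00251, adjusted p = 0.518 with an estimated correlation), with 7 higher and 2 lower in all lines and Atp6v0d1, a subunit of the acidifying proton pump, at 0.36 (SE 0.06), the 1 member that passed when adjusted over the list alone. Without 2838c3 the median was 0.06 and the call was lost (adjusted p = 0.118). DNA replication genes were lower (median -0.06 over 24 genes, 11 lower in all lines, camera adjusted p = 0.0101, adjusted p = 0.518 with an estimated correlation), with Pola1 at -0.21, Cdc6 at -0.19, Mcm6 and Uhrf1 at -0.15 and 0 passing when adjusted over the list alone, and the call was lost without 6419c5 (0.0884). MYC targets (median -0.05 over 25 genes, 8 lower in all lines, camera adjusted p = 0.0431, adjusted p = 0.562 with an estimated correlation) included Cad, Hspd1 and Dkc1 at -0.16 and Ncl at -0.15, and lost the call without 2838c3 (0.18) or 6499c4 (0.0923), with a median of -0.08 without 6419c5. Oestrogen receptor alpha response genes (median -0.11 over 8 genes, 4 lower in all lines, camera adjusted p = 0.0431, adjusted p = 0.518 with an estimated correlation) included Nrip1 and Ccnd1 at -0.19 and Bcl2 and Rara at -0.18. Their call was lost without 2838c3 (0.096), 6419c5 (0.225) or 6499c4 (0.0931). In both of these lists 0 members passed when adjusted over the list alone.

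Ribosomal protein genes (median 0.05 over 24 genes, camera adjusted p = 0.0188, adjusted p = 0.52 with an estimated correlation) had 5 members higher in all lines. Rpl27 (0.50, SE 0.09) and Rplp1 (0.31, SE 0.07) passed when adjusted over the list alone. Their median changed sign and the call was lost with quantile scaling (-0.02, adjusted p = 0.551) and with the GC and length correction (-0.05, adjusted p = 0.317). Without 2838c3 it was 0.02 and the call was lost too (adjusted p = 0.234). Without 6419c5 it was 0.10. Oxidative phosphorylation genes (median 0.06 over 20 genes, camera adjusted p = 0.028, adjusted p = 0.562 with an estimated correlation) had 2 members higher and 1 lower in all lines, with Cox7a2 at 0.18, Uqcrc2 at 0.09 and Sdha at -0.11 and 0 passing when adjusted over the list alone. Cox5b had a mean of 0.26 and was at -0.09 without 6499c4. The list's median was 0.01 without 2838c3 and 0.15 without 6419c5, and its call was lost without 2838c3 (0.301) or 6499c4 (0.162), with quantile scaling (0.139) and with the GC and length correction (0.615). In the integrated stress response list (median 0.02 over 23 genes, camera adjusted p = 0.0487, adjusted p = 0.912 with an estimated correlation), Cebpb (0.73, SE 0.16), Ddit4 (0.59, SE 0.11) and Atf5 (0.48, SE 0.08) passed when adjusted over the list alone, and Ddit3 was at 0.35. The median was -0.04 without 6419c5, 0.05 without 2838c3 and 0.08 without 6499c4. The call was lost in most alternatives, among them leaving out 2838c3 (0.161) or 6419c5 (0.871), no filter (0.0862), quantile scaling (0.0996), voom (0.0752) and the GC and length correction (0.235). With that correction in the FPKM test the list median was 0.04. These 3 lists held 0 members that passed over all genes.

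The other 14 tested lists did not pass with camera, and with fry none of the 25 passed (adjusted p of at least 0.113). Mitosis genes (adjusted p = 0.936) had Ube2c and Cenpa at 0.20 and Mki67 at -0.15, and p53 targets (0.105) had Bbc3 at 0.31 beside Gdf15. Endoplasmic reticulum chaperones (0.587), interferon-stimulated genes (0.79), MHC class I genes (0.79) and checkpoint ligands (0.72) had medians between -0.04 and 0.01. Among them Hsp90b1 was at -0.14, Tapbp at 0.30 (SE 0.09), H2-K1 at 0.21 (SE 0.06) and Cd276 at -0.15, and Bst2 (0.11) changed sign without 2838c3 (-0.13). Cytokine and NF-kB genes (0.766) held Csf1 beside Ccl20 at 0.28 and Cxcl2 at 0.20, and hypoxia and glycolysis genes (0.9) held Ndrg1 at 0.23 and Hk2 at -0.21. Epithelial genes (0.936) included Krt7 (-0.29, SE 0.06) and Krt8 (0.12), and mesenchymal genes (0.148) included Fn1 (-0.28, SE 0.06) and Cdh2 (-0.24, SE 0.06). Tubulin genes (0.577), with Tubb6 at -0.20 and Tuba1a at 0.19, passed after the GC and length correction (0.0452). NRF2 targets (0.149) had Hmox1 and Srxn1 at 0.18. Classical-type tumour genes (0.9, Sox9 at -0.35) and basal-like genes (0.936, Dhrs9 at -0.33) had camera directions opposite in sign to their medians of 0.03 and 0.07. The medians of mitosis, interferon-stimulated, MHC class I, checkpoint ligand, cytokine, hypoxia, epithelial, classical-type and basal-like genes changed sign in at least 1 alternative. Adjusted over the list alone, H2-K1, Tapbp, Csf1, Gdf15, Krt7, Cdh2 and Fn1 passed in their lists.

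Over all 10748 genes the responses of the 3 lines were weakly correlated. Each response sets 1 library against 1, so noise alone lowers these correlations, and they cannot show that the lines respond differently. Across genes, Pearson's r was 0.0507 for 2838c3 and 6419c5, 0.130 for 2838c3 and 6499c4, and 0.0729 for 6419c5 and 6499c4, with Spearman's rho of 0.105, 0.209 and 0.104. The mean r was 0.0845, and it was 0.0325 and -0.00195 with pseudocounts of 0.1 and 0.01 and 0.131 over genes with a mean of at least 5 FPKM. With the GC and length correction it was 0.0601. Of the genes, 1651 (15.4%) were higher and 1884 (17.5%) lower in all 3 lines, where chance gives 1 gene in 8 each. The standard deviation of the log2 differences was 0.26 in 2838c3, 0.24 in 6419c5 and 0.32 in 6499c4, and 71, 65 and 128 genes differed at least 2-fold. Short and GC-rich mRNAs were higher under G-1 in 2838c3 and 6499c4. Spearman's rho with GC content, across the 10368 genes where it was known, was 0.307 and 0.306, against -0.0850 in 6419c5. With gene length, across all 10748 genes, it was -0.278 and -0.259, against -0.0808 in 6419c5. The lines that share this tilt, 2838c3 and 6499c4, are also the pair with the highest correlation of responses.

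**Figure D3:**
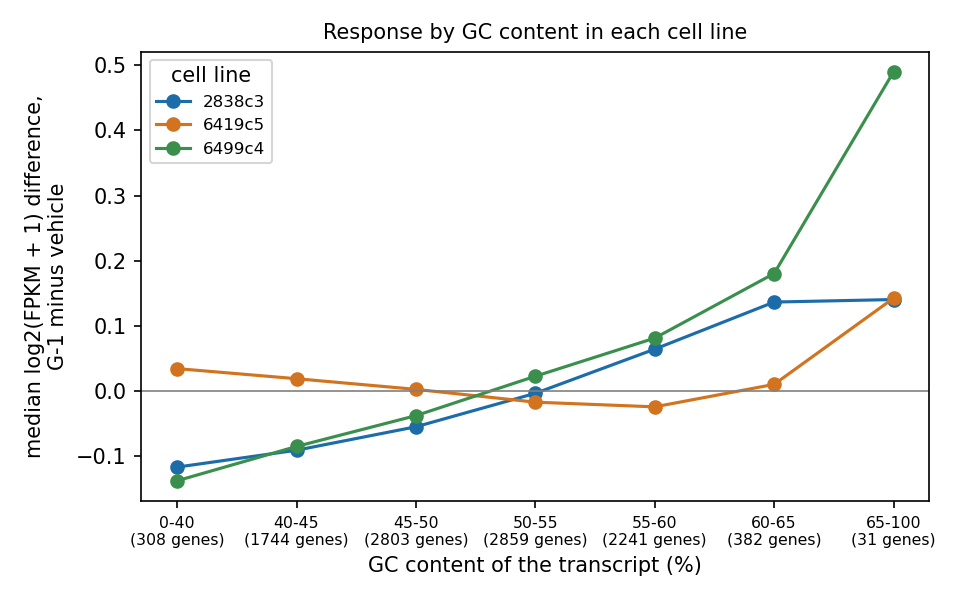
Median log2 difference (G-1 minus vehicle) of genes grouped by GC content (percent) in each of the 3 lines. From the lowest to the 60 to 65% group it goes from -0.12 to 0.14 in 2838c3 and from -0.14 to 0.18 in 6499c4, and in 6419c5 it is 0.03 and 0.01.

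Of 6 lists of markers of other cell types only Cd68 and Cd14 (macrophage), Esam (endothelium), Acta2 (fibroblast), Cela1 (acinar) and Pdx1 (endocrine) had a mean of at least 1 FPKM, and no lymphocyte marker did. Cd14 had means of 64.5, 56.8 and 43.4 FPKM in 2838c3, 6419c5 and 6499c4, Pdx1 0.182, 13.1 and 21.1, and Acta2 0.205, 180 and 2.30. Under G-1 the mean log2 differences of the 6 genes were 0.21, -0.23, 0.05, -0.20, -0.08 and 0.33 in the FPKM test, none with an adjusted p below 0.441. In voom Acta2 was lower by 0.655 (adjusted p = 1.54e-04), and by 0.651 with the GC and length correction (0.00861). Its read ratio was 0.611 in 6419c5 (4108 and 1913 reads, interval 0.578 to 0.645), and it had 5 and 4 reads in 2838c3 and 50 and 51 in 6499c4. Of the replication-dependent histone genes, whose mRNA lacks a poly(A) tail, 3 reached that level, and Hist1h2bc (0.56, SE 0.15) and Hist1h4i (0.04) stood beside Hist1h1c, with Hist1h1c and Hist1h2bc passing when adjusted over the list alone. Without 6499c4, Cd68 was at -0.30, Esam at -0.21 and Hist1h4i at -0.45. Cela1 was at 0.12 without 6419c5 and 0.14 without 6499c4, and Acta2 was at 0.05 without 6419c5. None of the 13 genes of the mitochondrial genome was in the table.

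The comparison between lines, which describes the background on which G-1 acted, gave far more differences than the treatment. In pairs, 5533 genes differed between 6419c5 and 2838c3 (51.5%; 2817 higher and 2716 lower in 6419c5), 5973 between 6499c4 and 2838c3 (55.6%; 2864 higher and 3109 lower in 6499c4) and 4836 between 6499c4 and 6419c5 (45%; 2291 higher and 2545 lower in 6499c4). Of these, 1076, 1398 and 1001 differed at least 2-fold. Without the vehicle or the G-1 library of 6419c5 the first count was 3430 or 3590 and the last 3003 or 2612. Each line rests on 2 libraries, 1 of them treated, so that the spread is that between treatments after the common effect of G-1.

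In 2838c3, Pax2, a transcription factor of kidney and duct development, was at 17.03 FPKM (SD 1.97, n = 2) against 0.246 in 6419c5 and 0.0361 in 6499c4, and the kidney cadherin gene Cdh16 at 14.8 (SD 1.85) against 0.0699 and 0. Sulf2 (25.5), Gjc1 (11.9) and the claudin gene Cldn2 (51.1) were high as well, against at most 0.917, 0.375 and 4.93 in the other lines. Ly6e was at 0 in both libraries and at 169 and 229 FPKM in 6419c5 and 6499c4. Prdx4, an endoplasmic reticulum peroxiredoxin (0 against 47.1 and 49.2), Maoa, monoamine oxidase A (0 against 43.2 and 66.3), and the brush border gene Cdhr5 (0 against 18.9 and 20.4) behaved alike. The intestinal transcription factor gene Cdx2 was at 0.0273 against 33.7 and 48.8, and the interleukin 1 receptor antagonist gene Il1rn at 3.35 against 199 and 109. Against both other lines 1732 genes were higher and 1611 lower in 2838c3, and these 11 had adjusted p from 1.35e-08 to 1.42e-05.

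In 6419c5, the homeobox gene Rhox5 was at 457 FPKM (SD 29.7, n = 2) against 0.073 in 2838c3 and 1.65 in 6499c4. Gatm, an enzyme of creatine synthesis, was at 164 (SD 2.38) against 0.0746 and 0. Acta2, smooth muscle actin and a marker of activated fibroblasts, was at 180 (SD 61.5) against 0.205 and 2.30. Klhl13 (43.6), B4galt4 (29.9) and Tm4sf5 (42.0) were the other genes highest in this line. Among the lowest were Bmp8b (0 against 14.9 in 2838c3 and 9.26 in 6499c4), the TEAD family gene Tead2 (1.29 against 37.5 and 15.8), the cartilage proteoglycan gene Acan (0.328 against 17.2 and 9.40), Clic6 and Ptk7. Against both others 1206 genes were higher and 915 lower, and the adjusted p of these 11 lay between 1.39e-07 and 2.29e-05.

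In 6499c4, the claudin gene Cldn18 was at 159 FPKM (SD 0.967, n = 2) against 0.75 in 2838c3 and 0.666 in 6419c5, and Agr2, a secretory disulfide isomerase gene, at 14.8 (SD 4.42) against 0 and 0.0921. Both are in the list of classical-type and gastric-lineage genes, which did not pass with camera against 2838c3 (adjusted p = 0.443) or 6419c5 (0.755). Nepn (144), Ifitm3, an interferon-induced transmembrane gene (73.1), the stathmin family gene Stmn2 (27.0) and Capn6 (20.5) were the others. The lowest were Tmem176a (0.258 against 84.3 and 57.2), Tmem176b (0.514 against 146 and 58.0), Trf, transferrin (0.431 against 33.4 and 106), Fxyd5 (1.18 against 56.7 and 72.9), the non-coding gene Xist (0.00653 against 28.3 and 25.7) and Ulbp1, a ligand of the receptor NKG2D (0 against 18.5 and 14.5). Against both others 1286 genes were higher and 1491 lower, and the adjusted p of these 12 lay between 3.51e-08 and 2.40e-05.

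**Figure D4:**
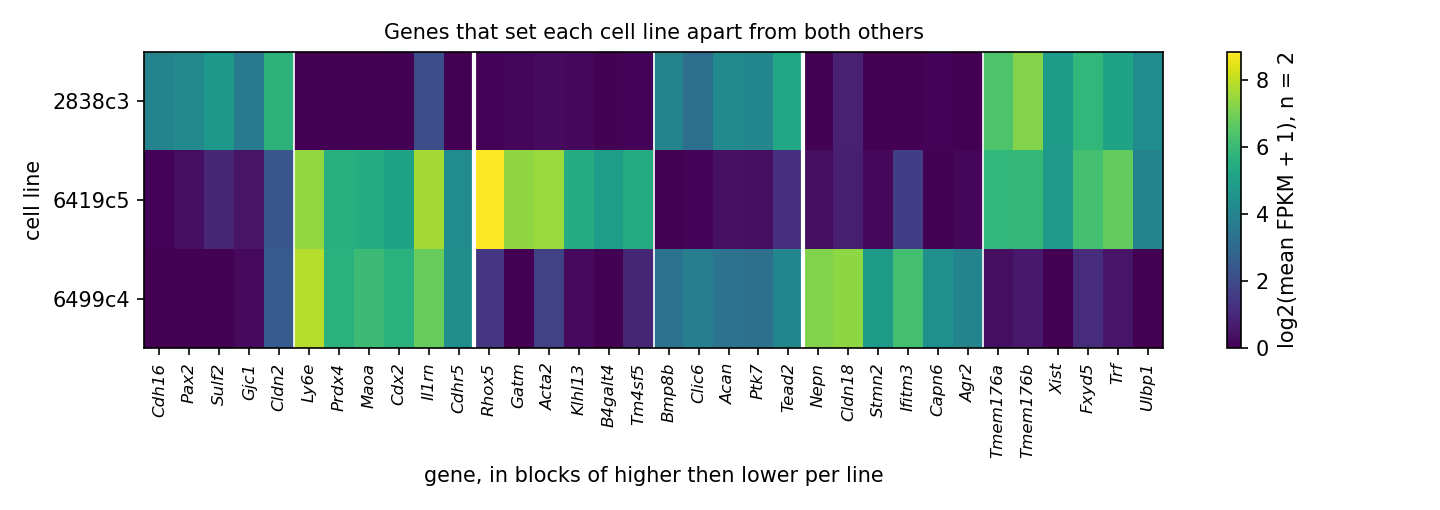
Mean FPKM of the 2 libraries of each line, as log2(mean FPKM + 1) in colour, for the genes named as highest and lowest in each line against both others (columns in blocks of higher then lower genes, with 1 row per line). Ly6e is at 0 in 2838c3 and has means of 169 and 229 FPKM in 6419c5 and 6499c4, and Cldn18 has a mean of 159 FPKM in 6499c4.

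Between 6419c5 and 2838c3, 4 lists passed with camera. Cholesterol genes were lower in 6419c5 (17 lower and 1 higher of 20, 19 passing when adjusted over the list alone, camera adjusted p = 4.98e-07), with Fdft1 at -1.67 (SE 0.09), Idi1 at -1.44 (SE 0.16) and Mvd at -1.42 (SE 0.10). DNA replication genes were lower (18 lower and 3 higher of 24, 23 adjusted over the list alone, camera adjusted p = 6.30e-04), with Mcm5 at -1.12 and Ccne2 at -1.06, and so were tubulin genes (5 of 10 lower, 8 adjusted over the list alone, camera adjusted p = 0.00784), with Tuba1a at -1.53. Mesenchymal genes were higher (6 higher and 1 lower of 9, 7 adjusted over the list alone, camera adjusted p = 0.0151), with Twist1 at 2.04, S100a4 at 1.84 and Sparc at 1.81. For each of the 4, adjusted p = 0.635 with an estimated correlation. Cd274 was higher in 6419c5 by 1.11 (SE 0.22, adjusted p = 0.00436), while checkpoint ligands as a list did not pass (0.581).

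Between 6499c4 and 2838c3, 8 lists passed. YAP/TEAD genes were lower in 6499c4 (12 lower and 0 higher of 14, camera adjusted p = 1.79e-05), with Thbs1 at -3.10 (SE 0.08), Cyr61 at -2.18 (SE 0.09) and Ankrd1 at -1.99 (SE 0.08). Cytokine and NF-kB genes were lower (13 lower and 2 higher of 19, camera adjusted p = 7.58e-04), with Cxcl3 at -3.31, Csf1 at -2.46 and Ccl2 at -2.34. Mitosis genes (17 lower and 1 higher of 24, 1.93e-04, Ccnb1 at -1.23), DNA replication genes (13 lower of 24, 0.00233), cholesterol genes (16 lower and 2 higher of 20, 4.48e-05, Msmo1 at -1.69, Fdps at -1.55) and tubulin genes (9 lower of 10, 8.61e-05, Tuba1a at -2.09) were lower too. Epithelial genes were higher (10 higher and 2 lower of 14, 0.00275), with Cldn3 at 3.90 (SE 0.19), Epcam at 1.91, Krt7 at 1.81 and Krt19 at 1.79, as were ribosomal protein genes (14 higher of 24, 0.00232, Rps27a at 1.08). Adjusted over the list alone the counts were the same except for DNA replication genes (14). For these lists adjusted p = 0.447 (YAP/TEAD, cytokine, DNA replication and epithelial) or adjusted p = 0.49 with an estimated correlation.

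Between 6499c4 and 6419c5, 12 lists passed, each with adjusted p = 0.409 with an estimated correlation. YAP/TEAD genes were lower in 6499c4 (13 of 14, camera adjusted p = 2.16e-08), with Thbs1 at -4.30 (SE 0.08), F3, tissue factor, at -3.40 (SE 0.09) and Cyr61 at -3.12 (SE 0.09). Mesenchymal genes were lower except Twist1 (8 lower and 1 higher of 9, 0.00142), with Sparc at -4.94 (SE 0.19) and Twist1 at 2.13 (SE 0.17). MHC class I genes (6 lower of 9, 0.00638, B2m at -1.26, H2-D1 at -0.84), interferon-stimulated genes (6 lower of 8, 0.00739, Bst2 at -1.24, Ifih1 at -0.91) and cytokine genes (11 lower and 3 higher of 19, 0.00728, Cxcl1 at -3.36) were lower. The cAMP/CREB list (11 lower and 1 higher of 16, 0.00142) had Ptgs2, the inducible cyclooxygenase gene, at -4.91 (SE 0.09). Mitosis (12 lower and 1 higher of 24, 0.00344), lysosome (12 lower and 1 higher of 20, 0.00344), tubulin (6 lower of 10, 0.00333) and aryl hydrocarbon receptor genes (3 lower of 5, 0.0176, Cyp1b1 at -2.27) were lower as well. Oxidative phosphorylation (11 higher and 1 lower of 20, 0.00638, Cox7a2 at 0.88) and ribosomal protein genes (14 higher and 1 lower of 24, 0.00269, Rpl10 at 0.73) were higher. Adjusted over the list alone the counts were the same except for interferon-stimulated (7), cytokine (16), oxidative phosphorylation (13) and ribosomal protein genes (17). Cd274 was lower by a log2 difference of -0.86 (SE 0.22, adjusted p = 0.0153). The lists that did not pass in a pair had camera adjusted p from 0.054 to 0.977, and fry, which tests whether a list's genes move one way on balance, called 14, 19 and 21 lists in the 3 pairs.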

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

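Chosen only after the data were seen were limma-voom on the recovered reads, the GC and length correction, both together, and the fit without small RNA genes. The number of genes called for G-1 depended on the processing more than those for the lines, and the numbers of lists changed in both. Of the 3 genes called for G-1, pseudocounts of 0.1 and 0.01 left 1 each, no filter and no variance trend left 0 each, a filter of 5 FPKM gave 6, robust moderation 8, the fit without small RNA genes 5, voom 181 and voom with the GC and length correction 30. Without the replicate block the count was 0, and leaving out a line gave 0 to 11. The 11 lists became 7 with the filter of 5 FPKM, 6 without the trend, 4 without the block and 5 to 8 without a line. The number was 0 with an estimated correlation or with fry. The estimated correlation gave 0 lists in every comparison, so its count cannot tell calls that hold from calls that do not. With the filter of 5 FPKM the aryl hydrocarbon receptor list kept fewer than 5 members and was not tested, so its absence there is no lost call, and the interferon-stimulated and basal-like lists were not tested either. Fewer degrees of freedom or more genes tested enter the counts without a line and without the filter. For the other changes the cause was not tested.

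Lists called between 6419c5 and 2838c3 (4) numbered 10 without the filter, 9 with voom, 0 with an estimated correlation and 14 with fry. The same last settings gave 0 and 19 for 6499c4 against 2838c3 (8), and 0 and 21 for 6499c4 against 6419c5 (12). Leaving out a library gave 3430 to 5677, 4480 to 5577 and 2612 to 4708 genes in these pairs. A line left with 1 library was assumed to vary like the others. The mean r between lines (0.0845) was 0.0325 and -0.00195 with pseudocounts of 0.1 and 0.01, 0.131 with the filter of 5 FPKM and 0.0507 to 0.130 without a line.

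None of the genes whose sign changed had passed in the FPKM test, and Acta2 passed in voom without (adjusted p = 1.54e-04) and with the GC and length correction (0.00861). Leaving out a line gave ranges of -0.0237 to 0.0208 for Myc, -0.262 to 0.104 for Cd274, -0.129 to 0.2501 for Bst2, -0.0352 to 0.189 for Pvrl2, -0.0942 to 0.529 for Cox5b, -0.0682 to 0.524 for Krt5, -0.0963 to 0.327 for Serpinb5, -0.446 to 0.344 for Hist1h4i, -0.3003 to 0.496 for Cd68, -0.207 to 0.237 for Esam, -0.3802 to 0.0497 for Acta2 and -0.505 to 0.137 for Cela1. The sign changed without 2838c3 for Myc, Cd274 and Bst2, without 6419c5 for Acta2 and Cela1, and without 6499c4 for Pvrl2, Cox5b, Krt5, Serpinb5, Hist1h4i, Cd68, Esam and Cela1. With the GC and length correction Bst2 (-0.0323) and Hist1h4i (-0.101) changed sign, with voom Cela1 (0.362), and with both Bst2 (-0.0506) and Cela1 (0.257). Among lists that passed, the median of the integrated stress response was -0.0401 to 0.0809 without a line (lowest without 6419c5) and -0.0199 with both, and that of ribosomal protein genes -0.0155 with quantile scaling, -0.0468 with the correction and -0.0555 with both. Among lists that did not pass, medians without a line were -0.0650 to 0.0267 for mitosis, -0.0705 to 0.0609 for interferon-stimulated, -0.0246 to 0.0438 for MHC class I, -0.0874 to 0.0189 for checkpoint ligand, -0.0176 to 0.0156 for cytokine, -0.0243 to 0.0594 for hypoxia, -0.0152 to 0.0352 for epithelial, -0.105 to 0.0566 for classical-type and -0.0963 to 0.105 for basal-like genes. The sign changed without 2838c3 for cytokine and hypoxia genes, without 6419c5 for checkpoint ligands and without 6499c4 for the others. It also changed with pseudocounts of 0.1 and 0.01 for epithelial (-4.55e-04 and -6.73e-04) and classical-type genes (-0.0121 and -0.0118), without the filter for cytokine genes (0.0214) and with the filter of 5 FPKM for epithelial genes (-0.0243). Quantile scaling changed it for hypoxia (-0.0424), epithelial (-0.0382) and classical-type genes (-0.00266). The correction did so for mitosis (0.0249), MHC class I (-0.0570), hypoxia (-0.0216), epithelial (-0.0481) and basal-like genes (-0.00199), and voom with the correction for mitosis (0.0297), MHC class I (-0.00822), hypoxia (-0.0202) and epithelial genes (-0.0506). The cause was not tested. Among named genes under G-1, 1879 values kept sign and side of the threshold, 52 gained and 20 lost a call. For list medians the numbers were 304, 2 and 34, with 32 that changed sign, and all 507 values of the genes named for the lines kept both. Depth limits genes with few reads, such as Snora81 and Cyp1a1.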

Other observations

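Chosen only after the result was seen were the tests of an effect on GC-rich or on short mRNAs common to the 3 lines, the random lists set beside the GC correlations, every value from limma-voom or the GC and length correction, and the genes of the first paragraph here. The 181 genes called by voom included the following, picked by hand, and lipid genes were not tested as a group. The desaturase gene Scd2 was higher under G-1 by 0.39 (SE 0.05, adjusted p = 1.35e-06), Scd1 by 0.26 (SE 0.06, adjusted p = 0.0105) and Srebf1, which encodes the factor that drives lipid synthesis, by 0.37 (SE 0.06, adjusted p = 4.45e-04). Cpt1a, the gate of mitochondrial fatty acid oxidation, was higher by 0.43 (SE 0.07, adjusted p = 1.14e-04), Acadl by 0.28 (SE 0.07, adjusted p = 0.0271) and the sterol exporter gene Abca1 by 1.59 (SE 0.26, adjusted p = 2.14e-04, 350 reads in all). Each had the same sign in all 3 lines. With the GC and length correction Scd2 (8.81e-05), Cpt1a (0.00439), Abca1 (0.00452) and Srebf1 (0.0355) stayed below an adjusted p of 0.05 in voom, and Scd1 (0.0919) and Acadl (0.0673) did not. The corrected log2 differences of Scd1 and Acadl were 0.24 and 0.29, so their size changed little. In the FPKM test Scd2 had an adjusted p of 0.206 and Cpt1a one of 0.216. The AP-1 gene Jun was higher by 0.67 (adjusted p = 0.00159), and Krt7 (-0.28, adjusted p = 0.00107) and Apob, a gene of lipid transport (-0.34, adjusted p = 4.16e-04), were lower.

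Some genes well expressed in a pair of lines had at most 3 reads over both libraries of the remaining line, with a mean of at least 5 FPKM in each of the others. There were 22 such genes in 2838c3 (21 without small RNA genes), 7 in 6419c5 (2) and 11 in 6499c4 (9). Besides genes named for the lines, they included Sox17 (0 reads in 2838c3, 7.37 and 30.0 FPKM in 6419c5 and 6499c4), Rab32 (0 reads in 2838c3, 18.4 and 27.3 FPKM), Dab2 (0 reads in 6499c4, 11.4 and 56.3 FPKM in 2838c3 and 6419c5) and Ces2g (0 reads in 6499c4, 9.89 and 19.4 FPKM). These examples were chosen after their values were seen.

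The higher level of aryl hydrocarbon receptor targets under G-1 was weighed against a library trend, counting noise and a ligand activity of G-1 on that receptor. After each library was corrected for GC content and gene length the list median was 1.00. The correction could hardly have lowered it much, since the medians of genes grouped by GC content lay between -0.14 and 0.18 up to 65% GC. Above that they were 0.14, 0.14 and 0.49. It is the small size of the GC trend, more than the correction, that argues against it as the cause. Of 15 read ratios by gene and line, 13 had an exact 95% interval above 1, which argues against counting noise. A set of 12 further genes known to respond to this receptor, chosen after the result of the first list but before their own values were seen, had 10 members tested (Nqo1 is also in the NRF2 list). Their median was 0.18, at percentile 99.9 of 10000 random lists matched for level, with 5 genes higher and 0 lower in all lines. None passed in the FPKM test (lowest adjusted p = 0.339). Pmm1 was higher by only 0.001 in 6419c5 and Ereg by 0.006 in 6499c4, and Nqo1 was at -0.36 in 6499c4. Any route that activates the receptor would raise such genes. The set therefore cannot tell an action of G-1, or of a product of it, on the receptor from another route. A route through GPER stays open as untested, since the design has no antagonist, no cells without the receptor gene and no other ligand. Reads of Gper1 were not detectable in any library at this depth, which does not exclude that route but leaves its receptor unmeasured.

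The cholesterol list was higher by 0.16 after the same correction. As for the receptor targets, the small GC trend left the correction little room to lower the median, so its outcome decides little. In 6419c5 the list median was 0.18, while medians by GC group lay between -0.02 and 0.03 up to 65% GC. That argues against a GC trend as the cause in that line, and a length trend was not weighed apart. No biological explanation was tested for the higher level of this list.

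The tilt toward short and GC-rich mRNAs in 2838c3 and 6499c4 was set against an effect of G-1 common to the lines and a technical source. The lowest of the 3 correlations with GC content, in 6419c5, was -0.0850, which argues against an effect on GC-rich mRNAs common to the lines as the whole cause, although the 31 genes above 65% GC had medians of 0.14, 0.14 and 0.49. The correlation with gene length was negative in each line (-0.278, -0.0808 and -0.259), so an effect on short mRNAs common to the lines stays open. Within functional lists of at least 15 members, 96.7% of the correlations with GC in 2838c3 and 6499c4 were positive, but so were 90.45% in random lists of the same sizes. That share therefore does not tell a GC-dependent recovery of fragments in single libraries from an effect of G-1 in 2 of the lines, and both stay open, since each library was made once.

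The libraries can be split in 4 ways that part every line's pair, too few for a share under 0.05. The real split gave 3 genes and the highest of the others 3, so that 2 of the 4 splits gave as many, and for lists the real split gave 11 and the highest of the others 5, so that 1 of the 4 gave as many. The remaining splits into 3 and 3, 6 of 10, put both libraries of a line in a group, and without the block each of the 10 called 0 genes in limma.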
